A study of Homo sapiens with 28 samples.

How the data were processed

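RNA sequencing of U937 cells gave 4 groups of 3 samples, and a genome-wide CRISPR knockout screen gave 8 groups of 2 populations. Poly(A) RNA was prepared as strand-specific paired-end libraries, per the labels' protocols. Per the submitters' processing notes, reads were aligned with STAR using the ENCODE options to hg38, counted with RSEM and compared with DESeq2. The versions of these tools and the gene annotation are not given in the sources used here, and whether counting used the strand is not given either. The authors deposited 1 table of 26475 genes per RNA comparison. Per the file headers and the submitters' processing notes, each deposited table holds 1 signal value per library, a normalized read count. Each also holds a log2 fold change with its standard error, a Wald statistic (a score), a p-value and an adjusted p-value, per the file headers. Multiplying each deposited library column by 1 constant returned whole reads in 100% of its values at a tolerance of 1e-06, so these values are counts divided by a size factor, and the recovered reads were used for depth, reads scaled to the library total (CPM) and edgeR. Replicate 1 of PMA-treated C9KO cells was not analysed here.

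For the screen, per the submitters' processing notes, guide counts of the day-12 populations were compared between genotypes with MAGeCK. The deposited MAGeCK tables hold a log2 fold change, a p-value and an FDR per gene and direction, per the file headers. The deposited casTLE tables hold an effect and a score per replicate and combined, and a p-value of the combined score, per the file headers. The smallest deposited casTLE p-value is 1e-05. Guide alignment, normalization, control guides and the scale of the casTLE effect are not given in the sources used here. Populations of day 3 were not used here.

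Because the values per library are normalized counts, the RNA comparisons were tested with limma's moderated test (trend) on log2 of the normalized count plus a pseudocount of 1, within each deposited table and over the genes to which the authors gave an adjusted p. P values were adjusted with the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15 and matplotlib 3.10.9 were used. The signs of the deposited RNA tables were set from the values per library so that positive means higher in C9KO or after PMA. The difference of the C9KO effect between the states was a z value from the deposited log2 fold changes and standard errors. Gene lists (41, fixed before the data were examined, tested where at least 5 members were measured) were tested with limma's cameraPR on the deposited statistic at a preset correlation of 0.01, and with camera at a correlation estimated from the libraries. In the screens the lists were tested with cameraPR on z values from MAGeCK's p-value, and casTLE's p-value was adjusted here over all genes. Overlaps were tested with Fisher's exact test. Gene positions came from a RefSeq annotation of GRCh38.p14, the build the labels call hg38, which placed 98.4%, 98.4%, 97.5% and 97.8% of the genes tested in the 4 RNA comparisons (C9KO before and after PMA, then PMA in control and in C9KO cells). Windows of 10 Mb with at least 15 genes of a base mean of at least 50 were summarised by their median log2 difference.

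The rule for named genes was set before the data were examined. In each RNA comparison it took the 12 highest and 12 lowest fold changes among called genes with a base mean of at least 100, and the 4 called members of each list with the smallest adjusted p. It also took C9orf72, SMCR8, WDR41 and FIS1 everywhere. In each screen it took the 10 genes with the smallest MAGeCK p and the 10 with the highest casTLE score in each direction, with the called members of the lists. For the difference of effects it took the 10 called genes with the smallest adjusted p in each direction, at a base mean of at least 100 averaged over both states. Some genes that the rule takes are not reported.

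The tests of the RNA comparisons were tested on simulated data, drawn for the real genes from the real libraries' means, with 100 genes changed at each fold size. Recovery of genes with few reads was not covered, because none of these was drawn among the changed genes. At a log2 fold of 2, limma recovered 80% of them for C9KO against control before PMA, 89% for the same comparison after PMA, 67% for PMA in control cells and 89% for PMA in C9KO cells. At a log2 fold of 1 it recovered 34%, 29%, 6% and 45% in the same order. Each draw changed 200 genes, whereas limma called 884, 1909, 7113 and 7088 genes in the real comparisons. The adjusted threshold is stricter with fewer changed genes. These recoveries therefore hold for such draws and do not measure detection in the real comparisons. Unchanged genes made up 5.00%, 7.09%, 1.35% and 10.7% of limma's calls in that order, and 4.24%, 11.1%, 5.13% and 9.74% of edgeR's, so the share was highest, and above 5%, in both comparisons with the 2 PMA-treated C9KO libraries. The test of the difference of effects recovered 94% of 200 changed genes at a log2 difference of 2, with 8 calls among the unchanged ones. Its errors were drawn from the deposited standard errors, and its changed genes from those with small standard errors in both states. The real z values spread more widely (median absolute deviation 1.30), so this draw does not show how many false calls the real test makes. The list test (15000 simulated genes), the adjustment of screen p-values (20000) and the window medians, overlaps and permutations (5000 each) were tested on random draws that are not of the real genes, and each recovered 100% of what was changed, with 0, 18, 5, 0 and 2 calls among the unchanged in that order. The paired check and the correlations were not tested this way. Recovered reads per library ranged from 7613229 to 35167307. The 10 highest genes took 4.92% to 5.64% of reads in undifferentiated libraries, 12.3% to 15.2% in PMA-treated control libraries and 8.59% and 9.57% in PMA-treated C9KO libraries. Guide counts per population were not used here, so the depth of the screen is unknown.

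Replicate numbers were checked as pairs by correlating, across 9932 genes, the deviations of same-numbered libraries from their group means. For PMA against undifferentiated control cells the correlations were 0.40, 0.44 and 0.56, so the numbers paired the samples by the data, while no label states a shared culture or day. A fit with the replicate number as a block called 9389 genes there. The alternatives were another threshold, a minimum fold, other filters and pseudocounts, the replicate block, leaving out each library, another list correlation and, chosen after seeing the data, edgeR's quasi-likelihood test with TMM on the recovered reads, the authors' adjusted p-values, a neuron and glia covariate and leaving out chromosomes 7, 15, 18 and 20.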

Results

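RNA was sequenced from U937 cells, a human monocytic leukaemia line, either control cells or cells with a knockout of C9orf72 (C9KO), and guide DNA was sequenced from a genome-wide CRISPR knockout screen in the same genotypes. C9orf72 is mutated in familial amyotrophic lateral sclerosis, and the series title names FIS1, a mitochondrial outer membrane protein of fission and mitophagy, as its genetic interactor. The 28 samples comprise 12 RNA samples in 4 groups of 3 (each genotype undifferentiated and after the phorbol ester PMA, which drives U937 cells towards macrophages) and 16 screen samples in 8 groups of 2. The RNA tables hold 11 libraries: C9KO PMA replicate 1 was not analysed here, so that group has n = 2. Recovered reads in genes ranged from 7613229 (control PMA replicate 2) to 35167307 (C9KO PMA replicate 2). In the undifferentiated state they were 12396109, 15796640 and 12652266 in control replicates 1, 2 and 3 and 10502131, 11540980 and 10682786 in C9KO replicates 1, 2 and 3. After PMA, control replicates 1 and 3 had 18554662 and 29047113 and C9KO replicate 3 had 9694275. The replicates are not stated to be separate cultures, so each p value of the RNA comparisons measures the spread between these samples. In the screen, cells of each genotype were infected with a library of 10 guides per gene and kept at about 1000 cells per guide. A part of each population was treated with 50 nM PMA for 3 days and collected on the fifth day. The 8 day-12 populations were compared, and the 8 day-3 populations were not used here.

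C9orf72 RNA (chromosome 9, 27546546 to 27573866, GRCh38) was present in every library, and it was lower in C9KO than in control cells after PMA. Before PMA it stood at 17.99, 21.97 and 21.02 CPM (reads scaled to a common library total) in control replicates 1, 2 and 3 and at 18.9, 12.9 and 14.3 CPM in C9KO replicates 1, 2 and 3. The group values were 20.3 CPM ± 2.08 and 15.4 CPM ± 3.10 (SD, n = 3 each), a log2 difference of −0.45 (SE 0.19) that did not pass limma's test (adjusted p = 0.236). After PMA, the control libraries held 34.4, 34.8 and 40.3 CPM and the C9KO libraries 16.3 and 18.1 CPM, a log2 difference of −1.10 (SE 0.18, limma adjusted p = 0.0200). This call was lost without C9KO replicate 2, C9KO replicate 3 or control replicate 2 (limma adjusted p = 0.0590, 0.126 and 0.0519), where the fold stayed between −1.19 and −1.01, and among other alternatives also with the neuron and glia level as a covariate (−1.09, limma adjusted p = 0.601). After PMA that level did not overlap between the genotypes, so the covariate cannot be separated from C9KO there. PMA raised C9orf72 in control cells by 1.15 log2 (SE 0.16, limma adjusted p = 0.00196), whereas the 0.51 log2 (SE 0.25) in C9KO cells did not pass (limma adjusted p = 0.144). The rise in C9KO cells was called with the replicate block and with the neuron and glia covariate. The C9KO effect on C9orf72 differed between the states by −0.68 log2, computed from the fold changes of the authors' deposited DESeq2 tables, which did not pass (adjusted p = 0.291). The position and kind of the edit are not given in the sources used here, so these values do not measure how complete the knockout was.

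**Figure D1:**
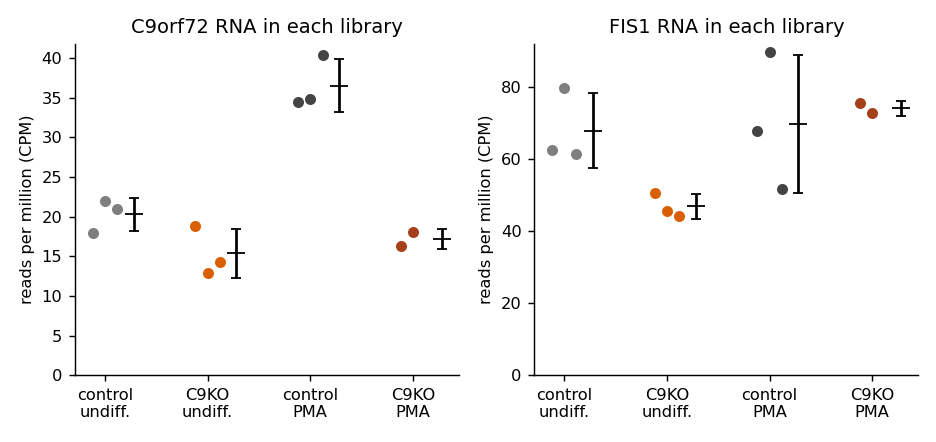
Recovered reads as CPM (vertical axes) of C9orf72 and FIS1 in each of the 11 RNA libraries (points), with the mean and SD of each group (black bars). C9orf72 lay at 34.4 to 40.3 CPM in the 3 PMA-treated control libraries and at 16.3 and 18.1 CPM in the PMA-treated C9KO libraries.

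SMCR8 and WDR41, the partners of C9orf72 in its complex, did not pass between genotypes in either state. Their log2 differences were −0.35 and −0.09 before PMA and −0.06 and 0.47 after it. With PMA, SMCR8 rose by 0.90 in control cells and 1.20 in C9KO cells, and WDR41 fell in control cells (−1.06, limma adjusted p = 0.0231). FIS1 (chromosome 7, 101239472 to 101245081) stood at 68.0 CPM ± 10.3 in control and 46.9 CPM ± 3.39 in C9KO cells before PMA (SD, n = 3 each), a log2 difference of −0.56 that did not pass (limma adjusted p = 0.0937). In the authors' deposited table the same comparison is −0.57 with an adjusted p of 0.0233. FIS1 lies in a stretch of chromosome 7, 100 to 110 Mb, whose genes had a median log2 difference of −0.69 between C9KO and control cells before PMA and −0.56 after it. After PMA, FIS1 stood at 69.7 CPM ± 19.1 in control (SD, n = 3) and 74.2 CPM ± 2.10 in C9KO cells (SD, n = 2). It rose with PMA in C9KO cells by 1.00 log2 (limma adjusted p = 0.000931), while its 0.32 in control cells did not pass. The C9KO effect on FIS1 differed between the states by 0.65 log2 in the authors' deposited values, which did not pass (z test, adjusted p = 0.335). A genotype difference in the PMA response of FIS1 was therefore not shown.

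Undifferentiated C9KO cells expressed less of most cholesterol genes than undifferentiated control cells, and a part of the MHC class II and interferon-response genes was lower, though no gene list passed with an estimated correlation. The comparison asks what differs between C9KO and control cells in the undifferentiated line. Stretches of several chromosomes, given below, were shifted in every C9KO library and in no control library. For any gene, loss of C9orf72 therefore cannot be told apart from other differences between the cultures. All 18 called genes of cholesterol synthesis and uptake, of 23 measured, were lower, among them MSMO1 (−2.18), MVD (−1.43) and CYP51A1 (−1.35). MHC class II genes fell in 4 of 9 cases, with HLA-DPB1 at −4.05, HLA-DRA at −3.75, their transactivator CIITA at −1.92 and the peptide-loading HLA-DMA at −1.81. Of 17 genes of MHC class I presentation 4 fell and 1 rose. The fixed list of B lymphocyte markers, 10 measured genes with FCER2 among them, summed to 183, 117 and 105 CPM in control replicates 1, 2 and 3 and to 28.3, 34.7 and 38.1 CPM in C9KO replicates 1, 2 and 3. The median marker of that list overlapped between genotypes (2.18, 1.08 and 1.66 CPM against 0.952, 1.30 and 1.08 CPM), so the sums are carried by a few of its genes. Of 39 interferon-response genes 7 fell, including RSAD2 (−2.14), OAS2 (−1.64), TRIM22 (−1.05) and SAMD9 (−0.99). The genes with the highest fold changes were PSTPIP2, an adaptor that restrains macrophage activation, at 7.84 (SE 0.40), the ubiquitin-conjugating enzyme UBE2C at 5.79 (SE 0.23), NT5C3B at 5.30, KIAA1211L at 5.24, the lymphoid transcription factor POU2F2 at 4.93 and SLAMF8 at 4.41. At the other end stood WHAMMP2 (−6.82), PDCD6IPP2 (−5.36) and GOLGA8M (−4.50), members of duplicated families on 15q whose reads can be split between copies and whose values are therefore uncertain. The IgE receptor FCER2 (−4.93), ANXA2R (−4.87), the protease inhibitor SPINT1 (−4.76) and ANKRD55 (−4.72) followed, as did RAPGEF6 (−4.53) and its neighbour on chromosome 5, CDC42SE2 (−3.86). By limma, 884 of 14616 tested genes passed, 294 up and 590 down, and each of the 884 also passes in the authors' deposited table, which calls 1684.

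Other fixed gene lists also held called genes in undifferentiated cells. Lysosomal genes fell in 10 of 53 cases and rose in 1, with NEU1 at −1.05 and ARSB at −1.06 against the lysosomal membrane protein TMEM106B at 0.98. Phagocytosis and complement receptors fell in 5 of 25 cases and rose in 1, with FCGR2B at −2.71, SCARB1 at −1.40 and ELMO1 at −1.16 against the efferocytosis receptor MERTK at 0.61. The chaperones of the endoplasmic reticulum HSPA5 (−1.01) and MANF (−1.45) fell within a list of ATF4 and ER stress genes (6 of 33 down, 1 up), while the mTORC1 inhibitor DDIT4 rose (adjusted p = 0.0117). Proteasome genes fell in 5 of 32 cases and mitophagy genes in 5 of 23. Of these, PSMC2 (−1.88), PSMA2 (−0.75), TOMM7 (−0.98) and the mitophagy adaptor TAX1BP1 (−0.84) lie on chromosome 7. Its stretches from 20 to 50 Mb and from 100 to 110 Mb are lower as a whole, so these falls may be regional. Proliferation genes rose in 5 of 51 cases, among them MYBL2 (1.05), GINS1 (0.92), PRIM1 (0.65) and MCM4 (0.53). The list counts do not leave out genes of shifted chromosome stretches. Other called genes, the proliferation and lysosomal genes included, can therefore also owe a part of their change to their position. When adjusted over the list alone, 21 cholesterol, 8 MHC class II, 9 interferon, 17 lysosomal, 11 phagocytosis, 10 ATF4 and ER stress, 6 proteasome and 8 mitophagy genes were lower and 9 proliferation genes were higher. With limma's cameraPR at a preset correlation of 0.01, 15 lists passed, 2 up and 13 down. The adjusted p was 1.8e-45 for cholesterol (median −1.21), 2.1e-05 for MHC class II (median −1.92) and 4.8e-05 for interferon (median −0.33). With an estimated correlation camera called 0 lists: the adjusted p was then 0.372 for cholesterol, MHC class II, lysosome and mitophagy, 0.229 for interferon, proteasome and phagocytosis, 0.377 for ATF4 and ER stress, and 0.708 for proliferation. Of 38 lists, 4 had an unadjusted p under 0.05 in that test.

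Neighbouring genes shifted together along several chromosomes in C9KO cells. Of 403 tested genes on chromosome 20, 72 rose where 7.99 were expected (Fisher's exact test, adjusted p = 7.5e-47 over 92 tests). On chromosome 7, 109 genes fell where 29.3 were expected (adjusted p = 1.2e-32, same Fisher test) and 30 rose where 14.2 were expected (adjusted p = 0.00133, same Fisher test). On chromosome 15 it was 73 against 21.4 (2.9e-19, same test), and on chromosome 18 it was 31 against 8.18 (2.6e-09, same test). These counts are of undifferentiated cells. After PMA the rise on chromosome 20 and the falls on chromosomes 7, 15 and 18 passed as well (adjusted p = 0.00300 or less, same Fisher test). The rise on chromosome 7 did not pass after PMA (44 against 39.5, adjusted p = 0.693, same Fisher test). Relative to the control mean, the median gene of chromosome 20 beyond 10 Mb lay between 0.39 and 0.48 log2 in the 5 C9KO libraries and between −0.02 and 0.01 in the 6 control libraries. Genes of distal 7p, up to 20 Mb, lay between 0.47 and 0.62 in the C9KO libraries and between −0.09 and 0.09 in the control libraries. Genes of 7p from 20 to 50 Mb lay between −0.82 and −0.74 in the C9KO libraries, those of 15q up to 60 Mb between −0.49 and −0.43, and those of 18q beyond 40 Mb between −0.56 and −0.46. Genes of chromosome 8 lay between 0.19 and 0.26 in the C9KO libraries, but also at 0.25 and 0.21 in control replicate 1 before and after PMA, and between −0.20 and −0.04 in the other control libraries. These regions were chosen after their values were seen. UBE2C lies in the chromosome 20 stretch and SPINT1 in that of 15q. Chromosome 9, which carries C9orf72, lay between −0.02 and 0.03 in every library. Without the genes of chromosomes 7, 15, 18 and 20, limma called 372 genes in place of 884. That fit and its adjustment were made anew over the genes left, so the drop is not the number of calls on these chromosomes. Leaving out C9KO replicate 3 left 46 calls, C9KO replicate 1 left 107, C9KO replicate 2 left 289 and control replicate 2 left 430. Control replicate 2 also had the lowest level of neuron and glia markers, 1.73 log2 against 3.91 to 5.81 in the other undifferentiated libraries.

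**Figure D2:**
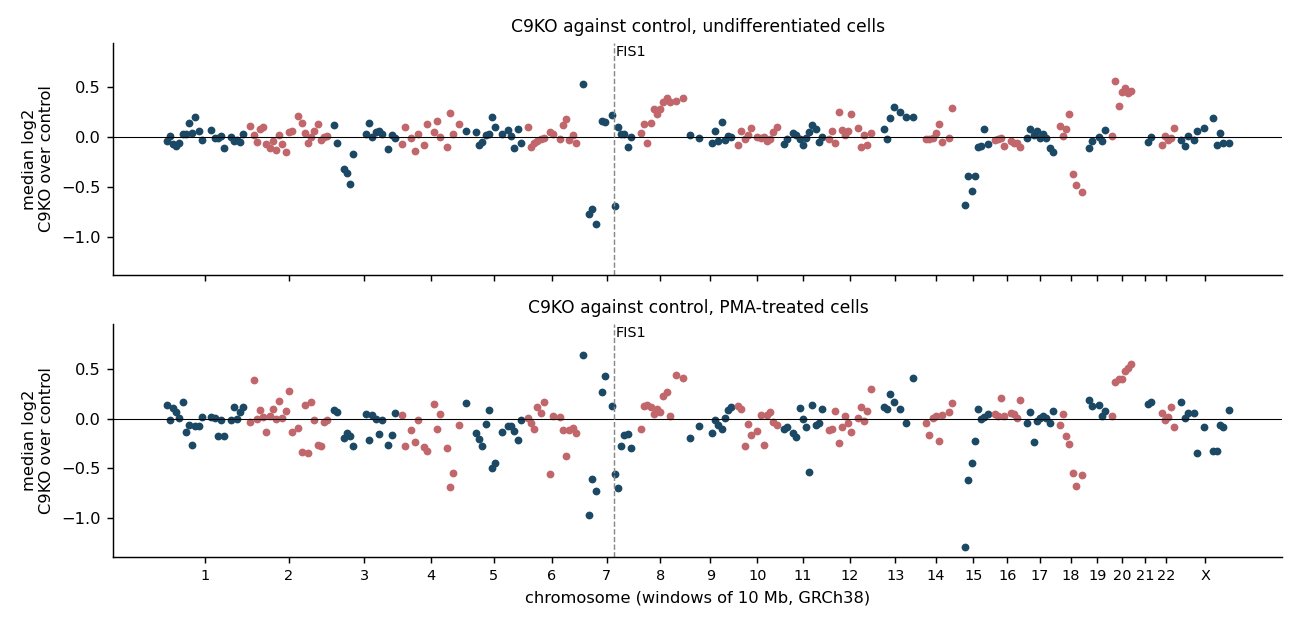
Median log2 difference between C9KO and control cells of the genes in each 10 Mb window along the chromosomes (horizontal axis, GRCh38), before and after PMA. The windows past 0.3 in both states with the same sign lie on chromosomes 7, 8, 15, 18 and 20, with the 100 to 110 Mb window of chromosome 7 that holds FIS1 at −0.69 and −0.56.

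PMA-treated C9KO cells expressed more of the genes of dividing cells than PMA-treated control cells, though no gene list passed with an estimated correlation. With the neuron and glia level as a covariate limma called 0 genes, but that level did not overlap between these genotypes. The comparison asks what differs between C9KO and control cells in the macrophage-like state. As before PMA, loss of C9orf72 cannot be told apart from other differences between the cultures. Proliferation genes were higher in 34 of 51 cases and lower in none by limma, with a list median of 1.47. TOP2A stood at 1.80, AURKA at 1.66, CENPF at 1.52 and BUB1 at 1.10. Here too, the list counts do not leave out genes that lie in shifted chromosome stretches. Interferon-response genes fell in 5 of 42 cases (list median −1.54), among them IFITM1 (−3.74), OASL (−3.53), SAMD9L (−2.61) and PLSCR1 (−2.05). That list did not pass with an estimated correlation, and its libraries differed: the CPM of its genes summed to 1815, 2538 and 7082 in control replicates 1, 2 and 3 and to 1665.6 and 1566.3 in C9KO replicates 2 and 3. Macrophage markers went both ways, 6 up and 8 down of 40: VSIG4 (4.13) and fibronectin FN1 (3.11) rose, and CD14 (−3.84) and GPNMB (−2.07) fell. Among the largest increases were the cytokine LIF (6.96, SE 0.93), ABCA13 (5.62), KRT3 (5.53), the bactericidal protein BPI (4.97), COL6A3 (4.47), MMP7 (4.34), S100B (4.27) and IL1R1 (4.26). Among the largest decreases were BIRC7 (−6.05, SE 1.53), the RNA sensor regulator DHX58 (−5.40), the complement subunit C1QC (−4.92), SIRPB2 (−4.61), MMP1 (−4.54), CD300E (−4.53), SIGLEC1 (−4.44) and ALCAM (−4.42). RAPGEF6 (−4.56) was among the lowest genes here as well.

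Cholesterol genes, lower in C9KO cells before PMA, were higher in them after PMA in 6 of 23 cases, with SQLE at 1.39, MSMO1 at 0.92, EBP at 0.76 and CYP51A1 at 0.72. Of 32 inflammatory genes 6 rose, including LIF, CCL5 (2.00), CSF1 (1.81) and TNFAIP3 (0.95), and 2 fell. Of 21 p53 targets 4 rose, among them the stress cytokine GDF15 (3.35) and SESN1 (1.42). CD74, the invariant chain of MHC class II, fell (−3.37). Mitochondrial ribosome genes rose in 4 of 67 cases, including MRPL14 (1.25) and MRPS10 (0.75), and proteasome genes rose in 2 and fell in 1 of 32, PSMB2 at 0.86, PSMA7 at 0.72 and PSMC2 at −1.29. Transcripts of neuron and glia markers fell in 7 of 12 cases, with GFAP at −1.66, AQP4 at −1.36 and MAP2 at −1.31. Their mean level did not overlap between the genotypes (5.47 to 6.22 log2 in control, 5.04 and 4.36 in C9KO libraries). A covariate of that level therefore cannot be separated from C9KO here. When adjusted over the list alone, 43 proliferation, 10 cholesterol, 9 inflammatory, 4 p53, 11 proteasome and 1 mitochondrial ribosome genes were higher, and 12 interferon and 11 neuron and glia genes were lower. By cameraPR at the preset correlation, 12 lists passed, 9 up and 3 down. Proliferation had an adjusted p of 2.0e-22, interferon 3.1e-07, neuron and glia 4.75e-06 and cholesterol 0.00249. With an estimated correlation camera called 0 of 40 lists, 0 also at an unadjusted p under 0.05 (adjusted p = 0.787 for the inflammatory list and 0.766 for the other lists named). In all, limma called 1909 of 15143 genes, 800 up and 1109 down, and edgeR called 1691. Leaving out C9KO replicate 3 left 106 calls, control replicates 2, 3 and 1 left 393, 651 and 1002, C9KO replicate 2 left 1210, and a limma fit with the neuron and glia level as a covariate called 0, with 1057 genes at an unadjusted p under 0.05 against 5188 without it.

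**Figure D3:**
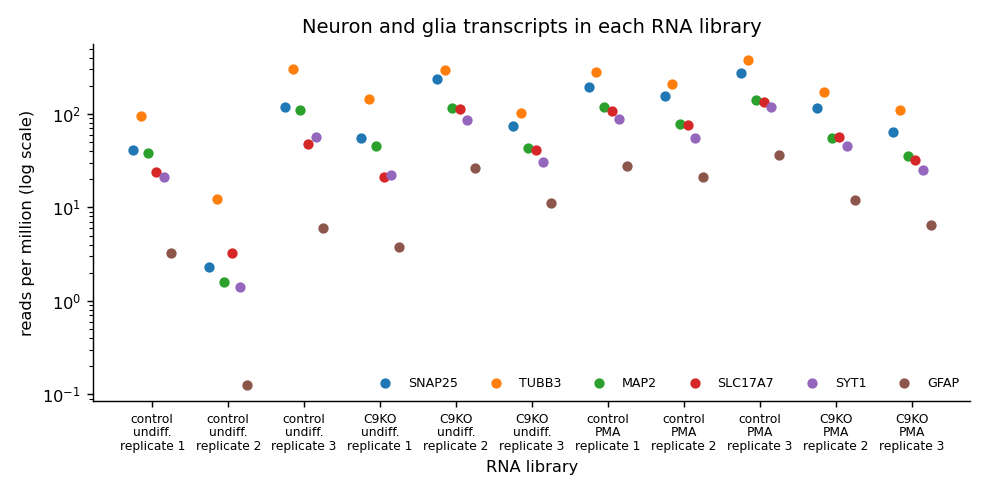
Recovered reads as CPM (vertical axis, log scale) of 6 neuron and glia markers in each of the 11 RNA libraries (horizontal axis). All 6 are lowest in undifferentiated control replicate 2, where SNAP25 stands at 2.28 CPM against 41.1 and 118 CPM in the other undifferentiated control libraries.

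The C9KO effect before PMA and the C9KO effect after PMA showed no correlation of a stable sign across genes, and they shared calls. Across 14196 genes tested in both states, which are not independent replicates, Pearson's r was −0.01 and Spearman's rho −0.06. At a base mean of at least 100 they were −0.03 and 0.10, and without chromosomes 7, 15, 18 and 20 they were −0.08 and −0.10. Among them 121 genes rose in both where 14.9 were expected (Fisher's exact test, p = 1.9e-80), 142 fell in both where 43.2 were expected (p = 5.2e-39, same test), and 17 went opposite ways. These expected counts hold for independent comparisons. Same-numbered libraries of the 2 states deviated together (r = 0.40, 0.44 and 0.56 in control and 0.50 and 0.46 in C9KO cells), so a part of the overlap can come from the libraries, and the excess is no measure of a shared effect. Outside chromosomes 7, 15, 18 and 20 the overlaps were 65 against 8.10 and 68 against 25.1. A test of the difference itself, which takes the 2 effects as independent, from the authors' deposited fold changes and standard errors, called 714 of 18234 genes, 559 with a more positive C9KO effect after PMA and 155 with a more negative one. The sterol enzymes MSMO1 (3.06), MVD (2.22) and CYP51A1 (2.07) were among the former, with the transcription factors SMAD3 (3.43) and IRF8 (2.05). The tryptophan dioxygenase TDO2 (−4.18), SIRPB2 (−4.15) and DDIT4 (−2.61) were among the latter. At an unadjusted p under 0.05 there were 2867 genes. With the z scaled by its median absolute deviation (1.30) 127 genes were called, and an interaction term in edgeR called 306, of which 298 were shared.

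After PMA, control cells expressed more macrophage, inflammatory and lysosomal genes and less of the genes of cell division and of myeloid granules, the comparison that sets the differentiation response. Macrophage markers rose in 33 of 41 cases and fell in 1 (list median 4.53), with SPP1 at 8.11, CD163 at 7.97, CD14 at 7.86, CD36 at 6.49, the growth factor receptor CSF1R at 6.37 and CHI3L1 at 5.45. Proliferation genes fell in 50 of 51 cases (list median −3.09), including E2F8 (−4.60), BUB1 (−3.21) and MCM3 (−2.45). Myeloid granule and progenitor genes fell in 19 of 27 cases and rose in 2: the granule proteases CTSG (−6.71), PRTN3 (−5.58), AZU1 (−5.00) and ELANE (−4.79) and the transcription factor MYB (−5.54) were among them. Inflammatory cytokines and chemokines rose in 25 of 34 cases and fell in 1, with CCL3L1 at 8.74 (SE 0.88), CXCL8 at 7.78, IL1B at 6.86 and CCL3 at 6.27. CCL3L1 has near-identical copies, and its value is therefore uncertain. Lysosomal genes rose in 41 of 55 cases, including cathepsin B, CTSB (3.79), the lysosomal cholesterol transporter NPC1 (2.93) and SCARB2 (2.53). Subunits of the vacuolar proton pump rose in 16 of 20 cases and fell in 1. Interferon-response genes rose in 24 of 41 cases and fell in 1, with OAS1 at 4.71 and IFI6 at 4.45. Cholesterol genes fell in 20 of 23 cases, with DHCR7 at −2.67 and CYP51A1 at −1.89. Neuron and glia markers rose in 5 of 12 cases.

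By limma 7113 of 17493 genes passed in control cells, 3524 up and 3589 down, and edgeR called 6693, 2750 up and 3943 down. The median gene lay 0.12 log2 above 0 under the authors' scaling and 0.02 above it under edgeR's TMM scaling. For the same comparison in C9KO cells it lay at −0.00 and at −0.15, and fold changes are relative to these. When adjusted over the list alone, 34 macrophage, 43 lysosomal, 17 proton pump, 27 inflammatory and 27 interferon genes rose, and 50 proliferation, 19 granule and progenitor and 20 cholesterol genes fell. By cameraPR at the preset correlation 20 lists passed, 12 up and 8 down. With an estimated correlation only the macrophage list passed (adjusted p = 0.0288), and with the replicate block added it did not (adjusted p = 0.235). The adjusted p with an estimated correlation was 0.306 for proliferation and lysosome, 0.0705 for the proton pump, 0.182 for the inflammatory list, 0.30 for granule and progenitor genes, 0.407 for cholesterol and 0.608 for interferon. A fit with the neuron and glia level as a covariate called 3569 genes.

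**Figure D4:**
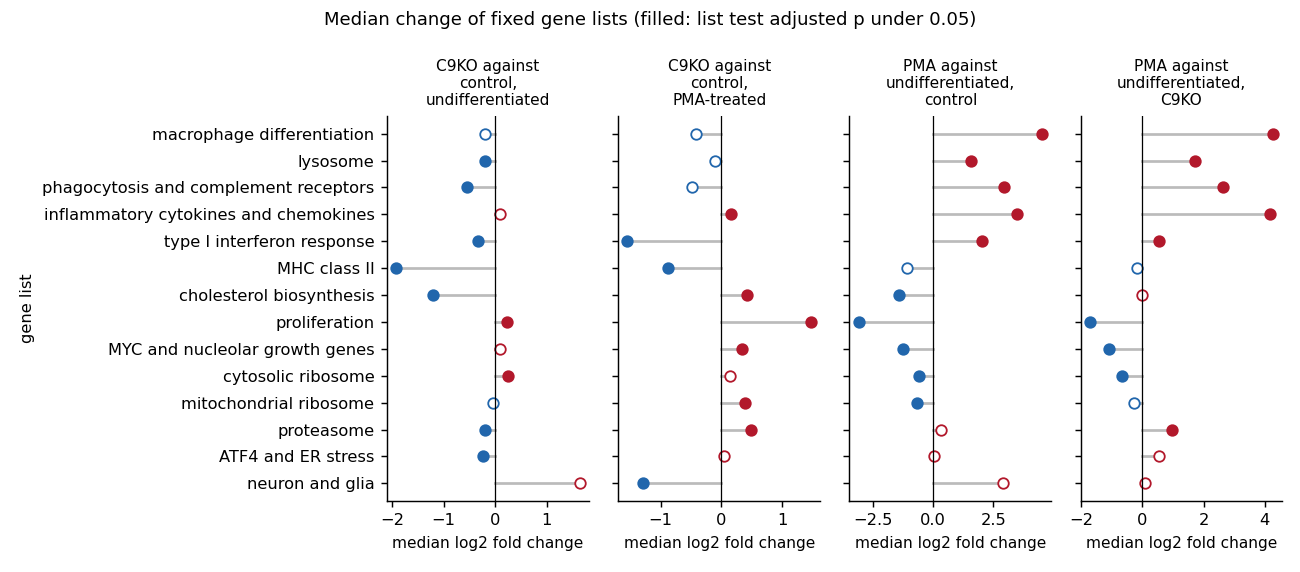
Median log2 difference of the members of fixed gene lists (horizontal axis) in the 4 RNA comparisons, with filled points where the list test at the preset correlation passed. Macrophage and lysosomal genes rose and proliferation genes fell with PMA in both genotypes, with proliferation medians of −3.09 in control and −1.71 in C9KO cells. With an estimated correlation the macrophage list with PMA in control cells alone passed, and not with the replicate block.

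In C9KO cells PMA also raised macrophage and lysosomal genes and lowered proliferation genes. Macrophage markers rose in 34 of 38 cases (list median 4.27), proliferation genes fell in 50 of 51 (list median −1.71), and lysosomal genes rose in 43 of 55 cases and fell in 1. CCL3L1 rose by 9.51, VSIG4 by 8.53 and MMP7 by 8.49, while MS4A3 stood at −6.79, PRTN3 at −5.99 and ELANE at −5.17. Proteasome genes rose in 30 of 32 cases (list median 0.96) and NRF2 target genes in 14 of 19, and cytosolic ribosome genes fell in 61 of 77 (list median −0.65). Cholesterol genes rose in 7 of 23 cases and fell in 3, with SQLE at 3.38 and MSMO1 at 1.70 among those that rose. When adjusted over the list alone, 35 macrophage, 44 lysosomal, 15 NRF2 and 31 proteasome genes rose, and 50 proliferation and 64 cytosolic ribosome genes fell. By limma 7088 of 16429 genes passed, 3632 up and 3456 down. By cameraPR at the preset correlation 22 lists passed, 17 up and 5 down, and 0 of 40 with an estimated correlation (4 at an unadjusted p under 0.05), where the adjusted p was 0.224 for macrophage, 0.478 for proliferation, 0.363 for lysosome, 0.363 for NRF2 targets, 0.506 for proteasome and 0.575 for cytosolic ribosome. Without C9KO PMA replicate 3, limma called 4310 genes. Across 16304 genes tested in both genotypes the PMA effects correlated with a Pearson r of 0.70 and a Spearman rho of 0.69. Of the calls 2360 rose and 2453 fell in both genotypes, and 26 went opposite ways.

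In the undifferentiated screen, which asks whose loss costs C9KO cells more or less fitness than control cells, MAGeCK called 12 of 20465 genes in the authors' deposited table. The tables do not name the direction of their signs. A negative value is read here as guides less abundant in C9KO cells because FIS1 is then depleted. That FIS1 is depleted is inferred from the series title, which calls the screen synthetic lethal and names FIS1 as interactor, so FIS1's own direction is not an independent finding and every direction given for the screens rests on this reading. Of these, 11 were in the higher direction, among them the splicing factor PHF5A (log2 fold change 0.83, FDR 0.0127), the ribosome recycling factor ABCE1 (0.42, FDR 0.0127) and the mitochondrial pseudouridine synthase RPUSD4 (0.57, FDR 0.0428). The other 8 of them carry clone-based names such as AC073657.1, and of these AC090673.2 has a negative log2 fold change (−0.60) in the authors' deposited table. The trace amine receptor gene TAAR8 was the call in the lower direction (−0.24, FDR 0.0495). At an unadjusted p under 0.05 there were 1684 genes in the higher and 592 in the lower direction. The casTLE tool called 0 of 20531 genes (smallest adjusted p 0.0821, computed here), with 2052 at an unadjusted p under 0.05.

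In the PMA screen, guides against FIS1 were less abundant in C9KO than in control populations and had the highest casTLE score of all genes. In the authors' deposited table FIS1 has a combined effect of −2.2 (deposited bounds −3.1 to −1.7), replicate effects of −2.0 and −2.3, and a score of 48.5; the scale of casTLE's effect is not stated. Its adjusted p, computed here with the Benjamini-Hochberg method from casTLE's p, was 0.0205, and 37 of 20529 genes passed, 26 in the higher and 11 in the lower direction. MAGeCK, in the authors' deposited table, places FIS1 at rank 4 in the lower direction with a log2 fold change of −0.61, a p of 0.000245 and an FDR of 0.987. MAGeCK called 0 of 20466 genes, with 1275 in the higher and 828 in the lower direction at an unadjusted p under 0.05, so no gene was called by both tools. Beside FIS1, the lower direction held the respiratory chain subunit UQCRC1 (−2.9), OR6C68 (−3.1), CCDC73 (−3.1), RWDD2B (−2.3), SS18L2 (−1.6), DTL (−1.6), the isoleucyl-tRNA synthetase IARS (−1.3), WDR36 (−1.3), DDX39B (−0.9) and NPTN (−0.8), by the combined casTLE effect of the authors' deposited table. Genes in the higher direction included, in the same deposited table, COX20 (2.6), the mitochondrial transcription factor TFAM (1.9), SUPV3L1 (1.9), MRPS18C (1.6), TAZ (1.6), MIPEP (1.5), C12ORF65 (1.5), TRMU (1.4), ATP5L (1.4) and COX6C (1.1). The segregase VCP (1.8), itself an ALS gene, the histone methyltransferase SETDB1 (2.1), DDX10 (1.9), MFAP1 (1.9), NPM1 (1.5) and MCM5 (1.3) were also higher. Those of the 37 that fall outside the rule for named genes were chosen after their values were seen. Held to the score that the threshold corresponds to for both replicates combined, 5 genes passed by replicate 2 alone and 4 by replicate 1 alone, and fewer calls follow by construction. In the authors' deposited table FIS1 has replicate scores of 13.4 and 35.8, so it passes that score by replicate 2 alone and not by replicate 1 alone.

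**Figure D5:**
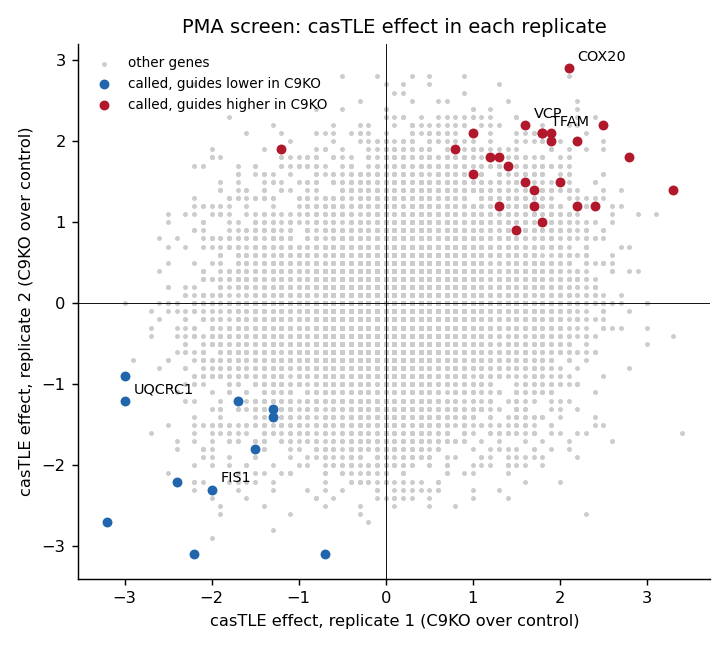
casTLE effect of replicate 1 (horizontal axis) against replicate 2 (vertical axis) for every gene of the PMA screen, from the authors' deposited table, with the 37 called genes marked. FIS1 lies at −2.0 and −2.3.

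FIS1 guides in the undifferentiated screen had a combined effect of −1.7 in the authors' deposited table (deposited bounds −3.7 to 0.3) with replicate effects of −1.8 and 0.2, a score of 3.07 and a p of 0.155, and MAGeCK gives it a log2 fold change of 0.04 there. Whether FIS1 differs between the screens was not tested. SMCR8 had an effect of −0.9 in the PMA screen (adjusted p = 0.351, computed here with Benjamini-Hochberg) and of 0.6 in the undifferentiated screen (adjusted p = 0.848, computed here with Benjamini-Hochberg) in the authors' deposited table, C9ORF72 guides had −0.3 in both screens, and WDR41 had 0. The casTLE effects of both replicates had the same sign in all of the 37 PMA calls but SETDB1, which is in part built in, since they were called by a score that combines both replicates. SETDB1 had opposite signs (−1.2 and 1.9 in the authors' deposited table). Across genes the replicate effects correlated weakly, with a Pearson r of 0.24 in the undifferentiated and 0.19 in the PMA screen. Between the screens the combined effects correlated with a Pearson r of 0.36 and a Spearman rho of 0.41, and 34 of the 37 PMA calls had the same sign before PMA. The PMA populations came from the infected cultures of the undifferentiated screen, so the screens are not independent.

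Guides against several gene lists, most of them of core growth functions, were relatively more abundant in C9KO populations in both screens, by cameraPR over 40 lists per screen on z values from MAGeCK's p. In the undifferentiated screen 8 lists passed, each higher, among them respiratory complex I (adjusted p = 2.2e-05, cameraPR), the mitochondrial ribosome (0.00729, cameraPR), the cytosolic ribosome (0.00177, cameraPR), the proteasome (0.00979, cameraPR) and proliferation (0.00949, cameraPR). The others were p53 targets (0.00729, cameraPR), MYC and nucleolar growth genes (0.0299, cameraPR) and the membrane-scission ESCRT genes (0.0365, cameraPR). Adjusted over the list alone, casTLE called 14 complex I genes higher and 1 lower, 24 and 2 of the mitochondrial ribosome, 11 and 2 of the cytosolic ribosome, and 12 and 4 of the proteasome. In the PMA screen 5 lists passed, each higher, among them the proteasome and proliferation (both 0.00263, cameraPR), the cytosolic ribosome (0.00289, cameraPR) and the mitochondrial ribosome (0.0131, cameraPR), where casTLE called 24 genes higher and 4 lower when adjusted over the list alone. MHC class II genes were the other list that passed there (0.0375, cameraPR), while complex I (0.750, cameraPR) and complexes III to V (0.712, cameraPR) did not. With a preset correlation of 0.05, complex I alone passed in the undifferentiated screen by MAGeCK (adjusted p = 0.0397, cameraPR) and none in the PMA screen. By casTLE's scores at that correlation, complex I (adjusted p = 0.00493, cameraPR) and the mitochondrial ribosome (0.00445, cameraPR) passed in the undifferentiated screen and the proteasome in the PMA screen (0.00308, cameraPR). An estimated correlation cannot be had from gene-level tables. Of the 35 genes called by casTLE in the PMA screen that were tested in RNA, 2 (CMAS and POLR3F) were also called between genotypes in PMA-treated RNA, where 4.61 were expected (Fisher's exact test, two-sided p = 0.312). Guides in the chromosome 7 window that holds FIS1 (113 genes) had a median MAGeCK log2 fold change of 0.0066 in the PMA screen against −0.0025 for the other genes, where the medians of whole chromosomes ran from −0.017 to 0.0060. In the undifferentiated screen it was 0.031 against 0.0038, above the highest median of a whole chromosome (0.026). Neither passed a permutation of the genes (permutation p = 0.118 before and 0.807 after PMA). Guides in the 9 windows higher in C9KO RNA in both states (636 genes) had a median of 0.026 against 0.0034 in the undifferentiated screen (permutation p = 0.000900, 0.00540 when adjusted over 6 tests) and of 0.0056 against −0.0026 in the PMA screen (permutation p = 0.0415, 0.124 when adjusted). Guides in the 10 windows lower in C9KO RNA in both states (590 genes), to which the FIS1 window belongs, had medians of 0.0036 against 0.0039 before PMA (permutation p = 0.952) and −0.0035 against −0.0024 after it (permutation p = 0.914). These permutations were chosen after the values were seen, and neighbouring genes are not independent.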

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

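The tests of the neuron and glia transcripts, of neighbouring genes and of guides against core growth genes were chosen only after the result was seen, as was the interaction term in edgeR. The z test of the difference of the C9KO effect and its scaled form were planned.

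The C9KO effect on RNA differed between PMA-treated and undifferentiated cells for 714 genes by the z test on the deposited fold changes, which is a difference between groups. With the z scaled by its median absolute deviation (1.30) it was 127 genes, and with an interaction term in edgeR 306. The C9KO effect was more positive after PMA, in log2, for MCTP2 (4.30), SMAD3 (3.43), CUX2 (3.39), the sterol oxidase MSMO1 (3.06), HMGA1 (2.25), MVD (2.22), RAB37 (2.17), CYP51A1 (2.07), IRF8 (2.05) and SERTAD2 (1.60). It was more negative for TDO2 (−4.18), SIRPB2 (−4.15), the Wnt receptor FZD4 (−3.38), ALCAM (−3.01), CREM (−2.72), DDIT4 (−2.61), N4BP2 (−1.83), GK (−1.46), IVNS1ABP (−1.30) and NBPF1 (−1.26). The interaction term called each of these 20 genes except ALCAM (adjusted p = 0.0525).

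Transcripts of neurons and glia were present in this myeloid line: SNAP25 stood at 41.1, 2.28 and 118 CPM in the undifferentiated control libraries, while MOG had no read in any library. PMA or C9KO as the whole cause of their presence is argued against, because 11 of 12 detected markers stood at 1 CPM or more in both undifferentiated control replicates 1 and 3, which had neither. RNA from other cells may be the source: 11 of the 12 were lowest in the same undifferentiated control library, replicate 2, where 5.73 are expected for the most frequent library if markers are independent, and 11 were lower in replicate 1 than in replicate 3. Genes regulated together would not be independent either. Whether PMA or C9KO changed their level cannot be told apart from differences between single libraries: the mean level ranged over 3.27 log2 among the 3 undifferentiated control libraries against 2.30 between group means, but over 1.09 against 1.39 without replicate 2. It also stays open whether such RNA entered at culture, extraction or sequencing, since no label gives a batch and no sort or gate is described.

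Whole stretches of chromosomes differed between C9KO and control cells in RNA. Copy number differences between the cultures are a candidate explanation: over 251 windows the C9KO shift correlated between the states (Pearson r = 0.571, Spearman rho = 0.181), and 19 windows passed 0.3 log2 with the same sign in both. Control libraries, which share their genotype, also differed from one another, over 26 windows before PMA. In each of 50 cases where a control library stood apart in a window, the same-numbered PMA library had the same sign. In 36 of them it also passed 0.3 log2. Each library was set against the mean of the others of its group, and most cases are neighbouring windows of chromosomes 7, 8 and 13. The 50 cases are therefore not independent. Loss of C9orf72 itself cannot be told apart from copy number for the shifts that every C9KO library shares, since undifferentiated C9KO libraries differed in just 3 windows and no DNA was measured. FIS1 lies in a stretch that is lower in C9KO cells in both states. Its own log2 difference was −0.56 before PMA and 0.11 after it, and neither passed limma's test. The undifferentiated 7q shift of control replicate 1 (−0.38 over 60 to 150 Mb) recurs in PMA control replicate 1 (−0.33). Both are relative to a control mean that includes replicate 1 itself. Set against the other control libraries, its window medians from 110 to 160 Mb were −1.52 to −1.29 before PMA and −1.18 to −0.92 after it.

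Guides against core growth genes were higher in C9KO populations. In the PMA screen a change in the need for mitochondria alone is argued against: of the cytosolic ribosome, proteasome and proliferation lists, 1 of 3, the proteasome, had a positive median and passed with preset correlations of both 0.01 and 0.05. This rests on casTLE (adjusted p = 0.00308 at 0.05), since by MAGeCK it did not pass at 0.05 (0.210). In the undifferentiated screen 0 of 3 passed at both by either tool, so a change in the need for mitochondria alone stays open there. Fewer divisions or less cutting in the C9KO populations stays open in both screens: that these lists passed in 6 of 6 tests at 0.01 is the pattern itself and decides nothing. In RNA after PMA, the mean log2 level of the proliferation list was 4.56 and 4.79 in C9KO and 3.92, 3.16 and 3.31 in control libraries. Before PMA the genotypes overlapped. These libraries are not the screen populations and do not count divisions, so they decide nothing here. Growth rates and Cas9 activity were not analysed here, and a biological effect of C9KO on growth stays open.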

How the results depend on the processing

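The fits with edgeR, the authors' adjusted p-values, the neuron and glia covariate, the chromosomes left out and the estimated correlations were chosen only after seeing the data; the other choices were made before the data were examined. Of 174 alternatives to 25 main results, 124 kept the direction and the side of the threshold, or stayed within 1.5 times the count, and 50 did not. Of 7764 alternative values of named genes 6654 kept both, 1099 lost the call, 5 gained it and 6 turned direction. Unless the setting itself shows it, the cause was not tested.

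At an adjusted p under 0.01 the counts were 127 for C9KO before PMA, 107 after PMA, 3902 for PMA in control cells and 338 for the difference of effects. A log2 fold of at least 1 left 343 for C9KO before PMA and 4449 for PMA in C9KO cells. The authors' deposited values call 1684 and 3386 genes for C9KO before and after PMA. Fitted and adjusted anew without chromosomes 7, 15, 18 and 20, the count before PMA was 372. With the z scaled by its median absolute deviation, 127 genes differed between the states, and with edgeR's interaction term 306.

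With the neuron and glia covariate limma called 974 genes for C9KO before PMA and 3569 for PMA in control cells. For C9KO after PMA it called 0 genes (1057 at an unadjusted p under 0.05), where the levels do not overlap between the genotypes. The covariate moved C9orf72 to −1.09 after PMA, no longer called, and to 0.49 for PMA in C9KO cells, then called. Values that had not been called turned direction: WDR41 to 0.10 before and −0.12 after PMA, and FIS1 to −0.56 and MAP1LC3A to 0.10 after PMA.

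The numbers did not pair the genotypes (r = −0.19, −0.80 and −0.65 before PMA, −0.12 and −0.18 after), and with 2 pairs PMA in C9KO cells was not judged. With the replicate block limma called 0 genes for C9KO before PMA (2277 at an unadjusted p under 0.05) and 580 after PMA, and C9orf72 stood at −1.18 after PMA, not called, and at 0.70 for PMA in C9KO cells, called. For PMA in control cells the block left 0 lists with an estimated correlation and changed no other call of a main result. In the screens the casTLE tables hold an effect per replicate number, so they already follow the numbers, and a fit without those pairs could not be made from gene-level tables. The MAGeCK tables pool both replicates, so no paired fit was made there.

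Leaving out 1 library gave 46 to 850 calls for C9KO before PMA (46 without C9KO replicate 3, 107 without C9KO replicate 1, 289 without C9KO replicate 2, 430 without control replicate 2). After PMA it gave 106 to 1210 (106 without C9KO replicate 3, 393, 651 and 1002 without control replicates 2, 3 and 1, and 1210 without C9KO replicate 2). For PMA in C9KO cells it gave 4310 (without C9KO PMA replicate 3) to 7885. The lone sample that this leaves is assumed to vary like the other group. C9orf72 after PMA stayed between −1.19 and −1.01 and lost its call without C9KO replicate 2, C9KO replicate 3 or control replicate 2. WDR41 before PMA lay between −0.22 and 0.034 (without control replicate 2), and FIS1 after PMA between −0.079 (without control replicate 3) and 0.34.

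With an estimated correlation 0, 0, 1 and 0 lists passed in the 4 RNA comparisons, and with a preset correlation of 0.05 there were 3 for C9KO after PMA, 1 in the undifferentiated and 0 in the PMA screen by MAGeCK, and 2 and 1 by casTLE. MAGeCK called 1 gene at an FDR of 0.01, 26 at 0.10 and 6 with at least 8 guides in the undifferentiated screen, and 2 at 0.10 in the PMA screen. casTLE called 5 at 0.10 in the undifferentiated screen and 0 at 0.01 in the PMA screen. Both tools together called 0 in either screen. The PMA screen by casTLE had 5 calls without replicate 1 and 4 without replicate 2, where FIS1 also lost its call (effect −2.0); a single score was held to the combined score's threshold, so fewer calls follow by construction. Leaving out a replicate was not run for MAGeCK, whose tables pool both, nor for casTLE in the undifferentiated screen, where no call sets a score. DESeq2 was not run here: it was planned only for deposited counts, and the authors' deposited adjusted p-values come from it.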

Other observations

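The comparisons of single libraries were chosen only after the result was seen; the splits of the libraries were planned.

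Several lists not described so far moved with PMA in both genotypes. Phagocytosis and complement receptors rose in 20 of 30 cases in control cells and 21 of 28 in C9KO cells (list medians 2.96 and 2.64). PKC and MAPK response genes rose in 22 of 29 and 23 of 29 cases (list medians 3.00 and 3.36), and integrin and adhesion genes in 18 of 26 and 19 of 26 (list medians 1.25 and 1.69). MYC and nucleolar growth genes fell in 23 of 25 and 20 of 25 cases (list medians −1.24 and −1.07), and genes of nucleocytoplasmic transport in 29 of 44 and 22 of 44 (list medians −0.62 and −0.49). With an estimated correlation the adjusted p in control cells was 0.0569 for phagocytosis, 0.133 for PKC and MAPK, 0.175 for integrins, 0.462 for MYC and 0.207 for nucleocytoplasmic transport (camera). In C9KO cells it was 0.239 for phagocytosis and integrins, 0.363 for PKC and MAPK and for MYC, and 0.662 for nucleocytoplasmic transport (camera).

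Among the 10 splits of the 6 undifferentiated libraries into 3 and 3, 1 split, the real one, called as many genes as the genotypes did (884 by limma, and 0 at most in the others). Among the 10 splits of the 6 control libraries by state, 1 split, the real one, did so (7113, and 0 at most in the others, 3 of which part as many same-numbered pairs and 6 of which part fewer). The splits are too few for a share under 0.05.

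Genes of 3p from 20 to 60 Mb lay at −0.55 in undifferentiated C9KO replicates 1 and 3 and at −0.42 in PMA-treated C9KO replicate 3, against −0.05 in undifferentiated C9KO replicate 2 and 0.06 in PMA-treated C9KO replicate 2. Genes of 13q beyond 40 Mb lay at −0.53 in undifferentiated control replicate 3 and at −0.39 in PMA-treated control replicate 3.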
